A study of Junonia coenia with 38 samples.

How the data were processed

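RNA-seq was done on whole wings of the buckeye butterfly Junonia coenia. Per the labels, animals were kept at about 27C, total RNA was taken from whole wing tissue, poly-A RNA was selected with NEB beads, and libraries were made with an NEB kit. The series lists 38 libraries. Of these, 24 are wing libraries: forewing and hindwing at the 5th larval instar, the prepupa, 72 h after pupation and a late pupal stage, with 3 libraries in each of the 8 groups. The late stage is given as 6 days after pupation in one label and as day 7 in another, and is called late pupa here. The count columns taken for the 72 h libraries are headed d3. They were matched by wing and replicate number, and d3 was taken to mean the same stage. The other 14 libraries carry labels that tie them to genome annotation, and were not analysed here. The labels of 4 of those contradict each other on the tissue, and they were put in no group.

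The authors deposited one table of counts, whole numbers of reads per gene model without normalization, for the 24 wing libraries. The submitters' processing notes name TopHat, bedtools and DESeq2, with no version and no role. The genome build, the annotation release and any use of strand are not given in the sources used here. The table holds 19234 gene models on 811 contigs, of which 488 have no count in any library. Each model is known by its contig and its first and last position, and the deposited files do not pair the models with gene names. Models are therefore named as contig:first-last. Positions count from 1, since 12 models begin at position 1 and 0 at position 0. Whether a count covers exons or the whole span is not stated. For 4 pairs of models the same coordinates are listed again. The spans of 3767 models overlap that of another model, and reads in such places can be divided between models or counted for both. Every count column was used.

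The lists of genes fixed before the data were examined (wing selectors, patterning, hormone response, pigment, cuticle, other cell types and more), and a label check by the hindwing selector Ubx, need gene names. None could be matched, so no gene list test was run. Near-identical gene copies could not be marked, and exons, introns and untranslated regions could not be assigned.

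Depth ran from 5795618 counts (hindwing, 72 h pupa, replicate 2) to 21284939 (forewing, 5th instar, replicate 3). Models with too few counts were removed with filterByExpr of edgeR (version 4.0.16, in R 4.3.3; minimum count 10, minimum total 15), which left 13282 models holding at least 99.9% of the counts of each library. TMM factors of edgeR scaled the libraries. A quasi-likelihood model (glmQLFit and glmQLFTest, two-sided) was fitted to all 24 libraries with a mean for each of the 8 groups, so that the groups share an estimate of the spread; the common biological coefficient of variation was 38.7%. A model was called when its Benjamini-Hochberg adjusted p was below 0.05. The contrasts were hindwing against forewing at each stage and as the mean of the 4 stages, each stage against the one before in each wing, and the change of the wing difference from stage to stage. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM from edgeR, the rate of counts per library total times its TMM factor, as mean ± SD of 3 libraries. Differences in these factors therefore enter every comparison of CPM. Where the lower group of a comparison held no counts, a fold is a bound against a floor of 3 counts over the group. Where it held 1 to 3 counts, the fold is the ratio of the rates with an exact 95% interval from the counts. PCR copies are not independent molecules, so bounds and intervals cover counting error only.

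Models to be named were chosen by a rule written before the data were examined. For a wing comparison they are the 2 called models highest in the hindwing and the 2 highest in the forewing by fitted log2 fold change, with a mean log2 CPM of 1 or more and no overlap between the CPM of the groups. For a stage step they are the 2 that rose most and the 2 that fell most by the mean of both wings, among models called in both wings in the same direction, with a mean log2 CPM of 3 or more and no overlap in either wing. Models outside the rule are marked as chosen after their values were seen.

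The replicate numbers come from the labels. Whether they pair samples was checked with deviations of log2 CPM from the group mean. Forewing and hindwing of the same stage and number correlated across models in all 12 pairs (r from 0.517 to 0.765), while different numbers of a stage reached at most −0.138. Deviations from a group mean cancel within the group, so negative values between different numbers follow from the positive ones. The evidence for pairing is that the same number ranked highest in all 12 pairs. The same numbers at consecutive stages lay between −0.0993 and 0.0847. Models are not independent replicates, and no p is given for these. The numbers were therefore taken to pair the wings of a stage and nothing across stages. For wing differences a fit with the replicate number of each stage as a block is given beside the unpaired one. For the stage steps the replicate block instead gives each number a term shared by all stages of a wing, a pairing that this check did not show. No label says that the 3 libraries of a group come from separate animals, so p-values measure the spread between these libraries. All 24 replicate pairs within groups differed by more than sampling noise (chi-square per degree of freedom from 29.4 to 359).

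The alternatives fixed at the start were DESeq2 size factors in edgeR, no filter on low counts, the DESeq2 (version 1.42.0) Wald test, a fit of only the groups compared, the replicate block, robust estimation of the spread, and leaving out each library in turn. Fits with only 2 of the 3 replicate numbers, and without both 72 h libraries numbered 3, were added after the data were seen. Apart from the replicate block for wing differences, none of these fits pairs the wings. The code was tested on simulated data with 100 models changed by 2-fold and 100 by 4-fold. All other models kept the same level in every group, and libraries were drawn without pairing. For hindwing against forewing in the prepupa (12827 models), 16% of 2-fold and 65% of 4-fold changes were recovered, and 6.90% of the calls were false. For prepupa against 5th instar in the forewing (12815 models) these values were 17%, 70% and 5.43%. For the change of the wing difference from 5th instar to prepupa (12827 models) they were 1%, 47% and 5.88%.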

Results

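Transcripts were counted in developing wings of the buckeye butterfly, in which forewing and hindwing grow as internal discs in the caterpillar and acquire scales and pigment in the pupa. The series title names the transcription factor spineless and EcR, the receptor of the moulting hormone ecdysone, in the chromatin landscape of wing metamorphosis. The wing libraries address how expression differs between the wings and changes from the last larval instar to the late pupa. Each of the 8 groups had 3 libraries. Total counts per library lay between 8678215 and 21284939 in the 5th instar, between 9282023 and 15256236 in the prepupa, between 5795618 and 13355152 at 72 h after pupation, and between 8316939 and 12775785 in the late pupa.

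The most abundant transcripts took a growing share of the counts as the wings matured. The 10 most abundant models held 9.41% ± 0.248 (SD, n = 3) of the counts in larval forewings and 8.66% ± 0.321 in larval hindwings. In the prepupa they held 20.5% ± 1.38 and 16.7% ± 1.78, at 72 h 23.8% ± 1.48 and 26.2% ± 1.97, and in the late pupa 30.9% ± 2.99 and 28.8% ± 2.00, forewing first. At 72 h, 000238F:382989-387955 alone took 7.16% ± 0.265 of forewing and 8.59% ± 0.398 of hindwing counts. Of the 10 leading models of a stage, the wings shared 9 in the 5th instar, 5 in the prepupa, 9 at 72 h and 8 in the late pupa. From one stage to the next, forewings shared 0 leading models in each of the 3 steps, and hindwings shared 2, 1 and 0. TMM factors averaged 1.67 and 1.75 in the larval groups, 0.590 and 0.870 in the prepupa, 0.953 and 0.844 at 72 h, and 0.897 and 0.942 in the late pupa, forewing first.

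**Figure D1:**
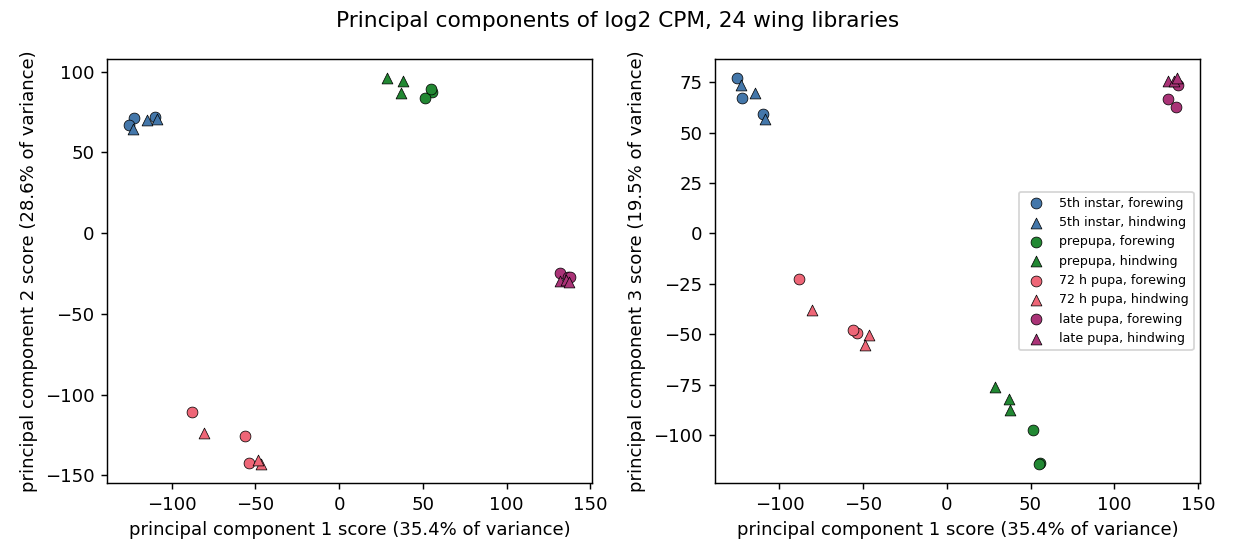
Scores of the 24 libraries on principal components of log2 CPM over 13282 models, component 1 (35.4% of the variance) against component 2 (28.6%) on the left and against component 3 (19.5%) on the right. Colour marks the stage, circles are forewings and triangles hindwings; libraries group by stage, and the wings stand apart in the prepupa.

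Within the 72 h stage, the libraries numbered 3 of both wings stood apart from the others. On component 4 (3.09% of the variance) they scored −82.9 in the forewing and −68.8 in the hindwing, against −2.53 to 73.0 for the other 72 h libraries. Their chi-square per degree of freedom against the other replicates of their group ran from 204 to 359, against 65.4 and 70.7 between numbers 1 and 2.

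Entry into the prepupa brought high levels of transcripts that were near absent in larval wings. The model 000143F:529976-535920 stood at 959 CPM ± 944 (SD, n = 3) in prepupal and 0.0458 CPM ± 0.0794 in larval forewings, a ratio of 22464 with a 95% counting interval of 7686 to 108941 on 3 larval counts. In hindwings it rose from 0.175 CPM ± 0.131 to 111 CPM ± 73.1, a log2 fold change of 9.17 ± 1.98 (SE; edgeR adjusted p = 0.000934). The model 000178F:690-8255 rose to 1029 CPM ± 646 in forewings (log2 13.34 ± 1.51, adjusted p = 5.66e-07) and to 217 CPM ± 180 in hindwings (log2 9.01 ± 1.26, adjusted p = 1.16e-05). In the other direction, 000053F:1475592-1488722 fell from 459 CPM ± 66.0 to 5.31 CPM ± 7.93 in forewings and from 514 CPM ± 63.8 to 0.563 CPM ± 0.392 in hindwings. The model 000116F:193666-199686 fell from 1679 CPM ± 335 to 26.5 CPM ± 30.8 and from 2056 CPM ± 271 to 8.72 CPM ± 1.91. Adjusted p-values for these falls lay between 7.64e-07 and 3.71e-05. Replicate 2 carried the prepupal forewing means of both, at 14.5 CPM against 0.581 and 0.881 for the former and 62.1 CPM against 9.68 and 7.78 for the latter. Without it the log2 fold changes were −9.26 in place of −6.37 and −7.60 in place of −5.97.

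Single libraries moved other fold changes of this step by over 1.5 times as well, and every call remained. In forewings the log2 fold change of 000143F:529976-535920 was 13.35 without larval replicate 3 and 12.92 without prepupal replicate 3. Without larval replicate 2 its larval forewings held 0 counts. The fitted value of 16.48 then depends on the prior count and is not a bound. For 000178F:690-8255 the log2 fold change was 13.95 without larval replicate 1, 12.73 without larval replicate 3 and 12.69 without prepupal replicate 2. In hindwings the former was at 9.90 without larval replicate 2 and 8.47 without prepupal replicate 3, and the latter at 9.61 without larval replicate 2 and 8.07 without prepupal replicate 2. The hindwing value of 000053F:1475592-1488722 was −10.54 without prepupal replicate 2, in place of −9.79.

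Of the 13282 models, 7416 were called between prepupal and larval forewings, 3448 higher and 3968 lower in the prepupa. In hindwings 6084 were called, 2837 higher and 3247 lower. With an absolute log2 fold change of 1 or more the counts were 5748 and 4270. Both wings called 2559 models up and 2812 down, against 736 and 970 for independent lists, and 14 in opposite directions; wings of one replicate number are paired samples, not independent ones. The majority direction rested on the scaling. DESeq2 size factors moved the median log2 fold change of all models by 0.19 in forewings and 0.12 in hindwings, and gave 3920 higher and 3321 lower models in forewings and 3132 and 2740 in hindwings.

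Between the prepupa and 72 h after pupation a further set of transcripts reached the top of the range. The model 000238F:282087-290733 rose from 2.22 CPM ± 1.04 to 13337 CPM ± 10956 in forewings and from 1.01 CPM ± 0.502 to 12746 CPM ± 4838 in hindwings (log2 12.57 ± 1.40 and 13.59 ± 1.45, edgeR adjusted p = 5.83e-07 and 3.39e-07). The model 000282F:339924-341373 rose from 2.01 CPM ± 0.562 to 4331 CPM ± 4309 and from 0.401 CPM ± 0.417 to 12036 CPM ± 11250 (log2 11.08 ± 2.00 and 14.76 ± 2.28). Replicate 3 at 72 h held less of these models than the others, 26.3 CPM in forewings and 100.02 CPM in hindwings of 000282F:339924-341373, and 701 and 7805 CPM of 000238F:282087-290733. The model 000001F:4705233-4709511 fell from 1241 CPM ± 805 to 0.141 CPM ± 0.126 in forewings (log2 −12.90 ± 1.56, adjusted p = 1.56e-06). In hindwings it was at 125 CPM ± 102 before and 0.186 CPM ± 0.212 after, a ratio of 924 with a counting interval of 316 to 4485 on 3 counts at 72 h. The model 000139F:1001198-1025653, whose values are uncertain because its span overlaps another model, fell from 13772 CPM ± 1513 to 4.18 CPM ± 5.04 and from 1498 CPM ± 768 to 3.37 CPM ± 4.02 (log2 −11.67 ± 1.75 and −8.86 ± 1.59). In all, 6364 models were called in forewings (3192 higher, 3172 lower) and 6444 in hindwings (3102 higher, 3342 lower). Both wings called 2400 up and 2421 down, against 745 and 798 for independent lists, and 47 in opposite directions. The forewing majority was narrow and turned under most alternatives, among them DESeq2 size factors, with 2978 higher and 3370 lower. Without both 72 h libraries numbered 3 the counts were 6304 and 6339.

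Leaving out single libraries ended no call of these 4 models but moved some fold changes by over 1.5 times. The log2 fold change of 000282F:339924-341373 was 10.10 without replicate 1 and 11.67 without replicate 3 of 72 h forewings, and in hindwings 16.08 without prepupal replicate 2 and 13.93 without 72 h replicate 1. That of 000139F:1001198-1025653 was −13.32 and −10.32 without replicate 2 of 72 h forewings and hindwings. In hindwings 000001F:4705233-4709511 was at −10.88 without replicate 2 and −8.88 without replicate 3 of the 72 h pupa, in place of −9.72.

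From 72 h to the late pupa, 000383F:322193-323813 rose from 0.313 CPM ± 0.272 to 4388 CPM ± 3233 in forewings and from 0.657 CPM ± 0.713 to 4472 CPM ± 3140 in hindwings (log2 13.74 ± 1.31 and 12.96 ± 1.28, edgeR adjusted p = 8.80e-08 and 1.36e-07). The model 000001F:4496359-4498016 stood at 742 CPM ± 386 in late forewings, a ratio of 8530 to its rate at 72 h (counting interval 2918 to 41364, 3 counts). In late hindwings it stood at 786 CPM ± 287, at least 6006-fold higher than at 72 h, where it had 0 counts. The model 000160F:1039013-1042994 stood at 558 CPM ± 49.0 and 708 CPM ± 246 at 72 h and kept 3 and 2 counts in late forewings and hindwings, ratios of 5320 (interval 1820 to 25802) and 8793 (interval 2434 to 72611). The model 000238F:490813-491607 fell from 2172 CPM ± 2132 to 0.201 CPM ± 0.214 and from 1472 CPM ± 2252 to 0.253 CPM ± 0.117 (log2 −13.28 ± 1.82 and −12.43 ± 1.77); replicate 3 carried both 72 h means, at 4625 CPM in forewings and 4072 CPM in hindwings against at most 1121 CPM in the others. This step called 6932 models in forewings (3422 higher, 3510 lower) and 6952 in hindwings (3436 higher, 3516 lower). Both wings called 2997 up and 3057 down, against 885 and 929 for independent lists, and 2 in opposite directions. The majorities were narrow and each turned under several alternatives, among them DESeq2 size factors in forewings, with 3476 higher and 3442 lower. Without both 72 h libraries numbered 3 the counts were 6776 and 6630, in hindwings with 3330 higher and 3300 lower.

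Every call of these 4 models remained when single libraries were left out, while fold changes moved by over 1.5 times in places. The log2 fold change of 000238F:490813-491607 was −12.08 and −9.33 without replicate 3 of 72 h forewings and hindwings, and −14.25 without replicate 2 of late forewings. For 000383F:322193-323813 it was 13.15 without replicate 3 of 72 h forewings, and in hindwings 14.18 without replicate 2 and 12.29 without replicate 3 of the 72 h pupa. The fitted value of 000001F:4496359-4498016 in forewings went from 12.84 to 16.16 without replicate 2 of the 72 h pupa, which left 0 counts at 72 h. The size of 16.16 depends on the prior count and is not a bound. For 000160F:1039013-1042994 the fitted value was −13.12 without replicate 2 and −11.57 without replicate 3 of late forewings, in place of −12.23. In hindwings it was −16.11 without replicate 1 of the late pupa, in place of −13.05. That left 0 late hindwing counts, so the size of −16.11 depends on the prior count as well.

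Over the 3 steps, 9625 models (72.5% of those tested) changed in the same direction in both wings at least once, and 1628 were called in no step of either wing. By the stage of highest mean log2 CPM over both wings, 2837 of the 9625 were highest in the 5th instar, 2007 in the prepupa, 2368 at 72 h and 2413 in the late pupa. Each wing taken alone was also highest at that stage for 91.2%, 78.7%, 87.5% and 88.0% of these models, in stage order. A lead of at least 3 on the log2 scale over the next stage was held by 96 of the larval, 254 of the prepupal, 304 of the 72 h and 423 of the late pupal models. This grouping describes the means and is not a test.

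**Figure D2:**
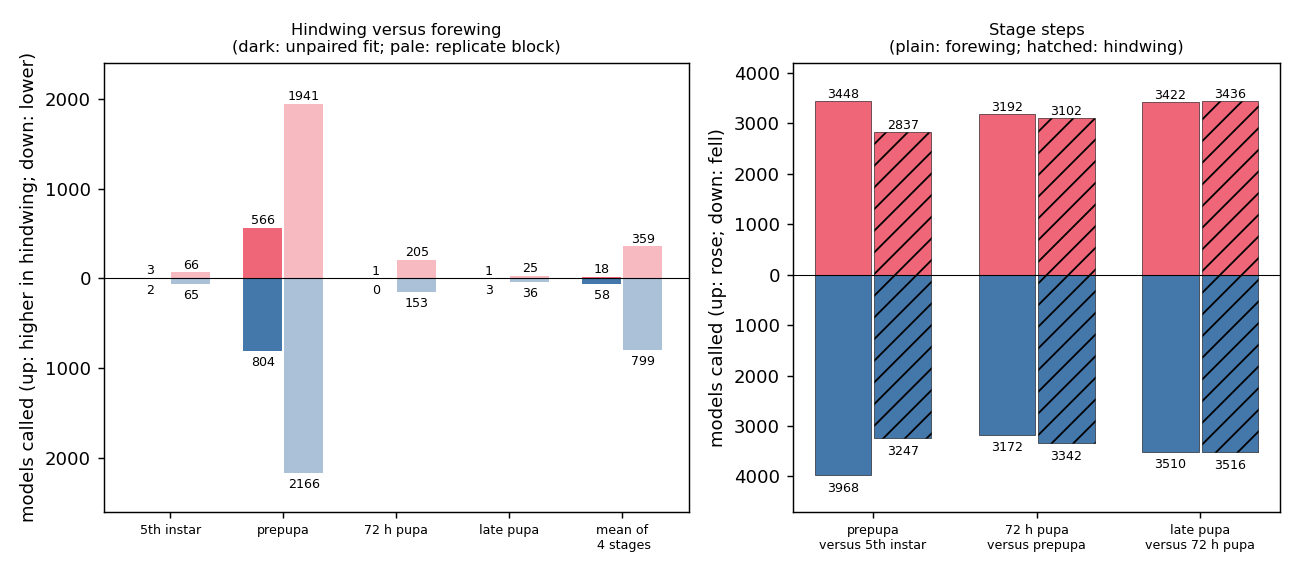
Models called at an adjusted p below 0.05 (edgeR), as bars of counts from 0 on linear axes: upward for models higher in the hindwing or rising, downward for models lower or falling. The left panel shows wing comparisons without (dark) and with (pale) the replicate block, 566 and 1941 higher models in the prepupa; the right panel shows stage steps in forewing (plain) and hindwing (hatched), the shortest bar standing for 2837 models.

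One model was called between the wings at every stage in the fit of all groups, 000025F:951192-952313. It stood at 37.1 CPM ± 2.67 (SD, n = 3) in larval hindwings against 0.471 CPM ± 0.0372 in larval forewings, and at 41.6 CPM ± 4.90 against 0.328 CPM ± 0.274 in the prepupa. At 72 h it stood at 7.21 CPM ± 1.65 against 0.0647 CPM ± 0.0582 and in the late pupa at 6.26 CPM ± 1.28 against 0.0711 CPM ± 0.123. The log2 fold changes were 6.28 ± 0.42 (SE), 6.80 ± 0.47, 6.64 ± 0.56 and 6.29 ± 0.56 in stage order (edgeR adjusted p = 1.06e-07, 6.24e-08, 4.98e-06 and 1.39e-05), and with the replicate block 6.26 ± 0.22, 6.80 ± 0.29, 6.63 ± 0.44 and 6.25 ± 0.45. Forewings held 2 counts at 72 h and 2 in the late pupa, so the ratios there, 113 and 89.8, have counting intervals of 30.9 to 945 and 24.5 to 747. At these 2 stages it falls outside the naming rule and was chosen after its values were seen. Its calls there ended in fits of only the groups compared (adjusted p = 0.222 at 72 h and 0.129 in the late pupa, the highest of the alternatives) and with numbers 2 and 3 of every group. The log2 fold change was 7.88 without forewing replicate 2 in the prepupa, and 5.64 without forewing replicate 3 in the late pupa. Without forewing replicate 2 the late forewings held 0 counts. The fitted value of 9.29 then depends on the prior count and is not a bound.

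In the 5th instar, 5 models differed between the wings, 3 higher and 2 lower in the hindwing. Besides 000025F:951192-952313, the model 000232F:434614-437944 was higher in hindwings, at 8.82 CPM ± 2.66 against 1.55 CPM ± 0.113 (log2 2.50 ± 0.35, edgeR adjusted p = 0.00369). So was 000029F:1833570-1858475, chosen after its values were seen, at 2.23 CPM ± 0.653 against 0.0725 CPM ± 0.0175 (log2 4.78 ± 0.77, adjusted p = 0.0205). The model 000129F:89294-91831 was lower in hindwings, at 3.77 CPM ± 1.19 against 22.98 CPM ± 4.63 (log2 −2.60 ± 0.33, adjusted p = 0.00158), as was 000037F:2356736-2361176, at 2.997 CPM ± 0.530 against 10.4 CPM ± 1.03 (log2 −1.79 ± 0.31, adjusted p = 0.0364). With the replicate block 131 models were called, 66 higher and 65 lower, including all 5. The unpaired count was 2 without forewing replicate 2 or 3, 3 without forewing replicate 1 or hindwing replicate 1 or 2, and 4 without hindwing replicate 3. In the unpaired fit the call of 000037F:2356736-2361176 ended whichever of the 6 libraries was left out (adjusted p from 0.111 to 0.242). That of 000029F:1833570-1858475 did so too (from 0.0533 to 0.442). That of 000232F:434614-437944 ended without forewing replicate 2 or 3 (adjusted p = 0.0715 and 0.0602). With all libraries and the replicate block, edgeR adjusted p was 0.000653, 0.00145 and 0.000850 for these models, in this order.

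The prepupa showed by far the most wing differences. The model 000000F:5746111-5748168 stood at 1591 CPM ± 265 in hindwings and 19.5 CPM ± 9.47 in forewings (log2 6.34 ± 1.52, edgeR adjusted p = 0.0103; 6.40 ± 0.49 with the replicate block). A pair of models on one contig was higher in forewings. The model 000057F:507839-512115 stood at 0.567 CPM ± 0.212 in hindwings and 21.1 CPM ± 5.07 in forewings (log2 −5.18 ± 0.81, adjusted p = 0.000513; −5.17 ± 0.28 with the block). The model 000057F:536747-539676 stood at 15.7 CPM ± 11.4 and 337 CPM ± 79.3 (log2 −4.43 ± 0.67, adjusted p = 0.000282; −4.67 ± 0.41 with the block). Together 1370 models were called, 566 higher and 804 lower in the hindwing, of which 261 and 481 had an absolute log2 fold change of 1 or more. The balance of directions shifted with the processing. It was 453 higher and 941 lower with DESeq2 size factors, and 647 and 1222 with the DESeq2 Wald test. The replicate block called 4107 models, 1941 higher and 2166 lower, including all 1370. Without forewing replicate 1 or hindwing replicate 3 the unpaired count was 863 or 858. The unpaired call of 000000F:5746111-5748168 ended without forewing replicate 1 or 3 (adjusted p = 0.0610 and 0.0516). With all libraries and the replicate block, the edgeR adjusted p of this model was 2.94e-06.

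**Figure D3:**
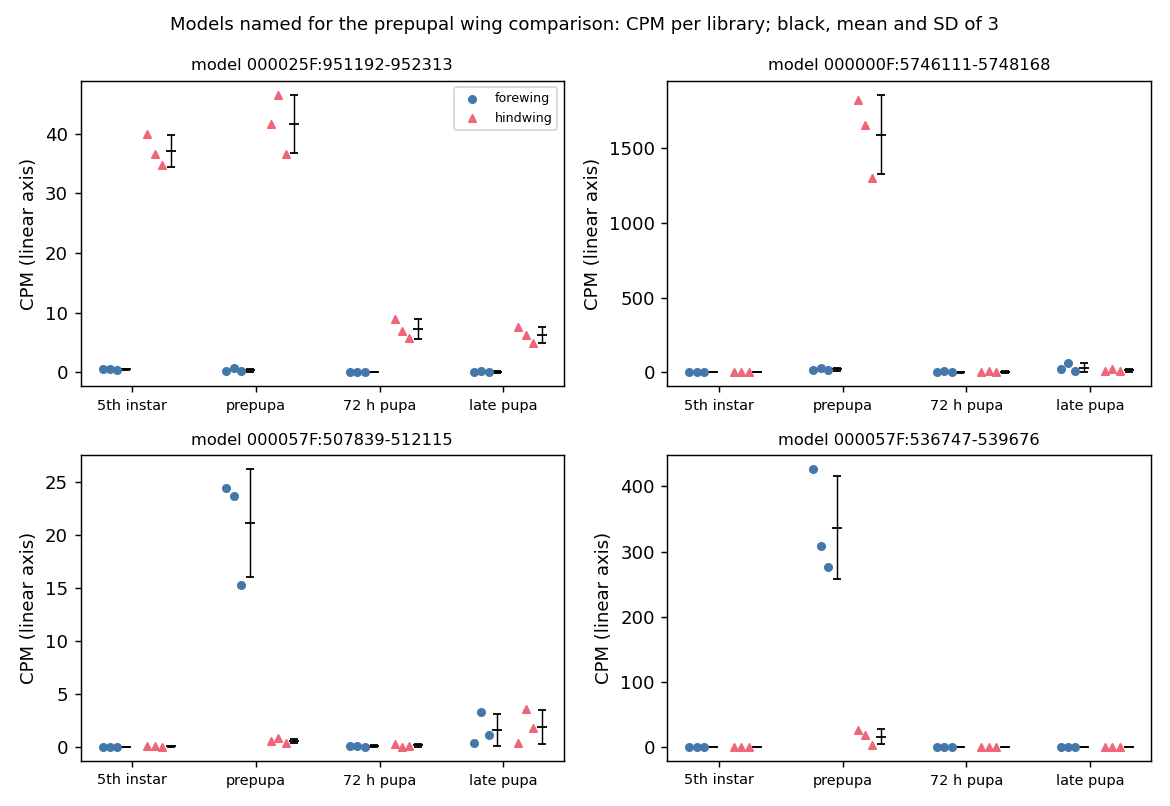
CPM per library on linear axes for the 4 models named in the prepupal wing comparison, by stage; circles are forewings, triangles hindwings, and black bars give mean and SD of 3 libraries. In the prepupa 000025F:951192-952313 and 000000F:5746111-5748168 are higher in hindwings, at 41.6 and 1591 CPM, and both models on contig 000057F are higher in forewings, at 21.1 and 337 CPM.

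At 72 h after pupation 000025F:951192-952313 was the only model called between the wings by the unpaired edgeR test; 512 models had an unadjusted p below 0.05. The replicate block called 358 models, 205 higher and 153 lower in the hindwing, and the DESeq2 Wald test called 23. Without hindwing replicate 3 the unpaired count was 131, without forewing replicate 3 it was 8 and without hindwing replicate 2 it was 5. Without both libraries numbered 3 it was 66, and an edgeR fit of the 72 h groups alone called 0 models.

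In the late pupa 4 models differed between the wings. Besides 000025F:951192-952313, all were lower in hindwings. The model 000078F:105509-119301 stood at 4.57 CPM ± 3.94 against 136 CPM ± 89.2 in forewings (log2 −4.90 ± 0.74, edgeR adjusted p = 0.0126; −4.75 ± 0.59 with the replicate block). The model 000009F:2925635-2927721 stood at 29.0 CPM ± 13.3 against 327 CPM ± 119 (log2 −3.49 ± 0.50, adjusted p = 0.00930; −3.54 ± 0.19 with the block). The model 000017F:2036946-2042642, chosen after its values were seen, stood at 4.79 CPM ± 0.880 against 24.6 CPM ± 15.98 (log2 −2.36 ± 0.37, adjusted p = 0.0149). The block called 61 models, 25 higher and 36 lower, and the DESeq2 Wald test 19. Without forewing replicate 1, hindwing replicate 2 or hindwing replicate 3 the unpaired count was 2, and an edgeR fit of the late groups alone called 0, against 254 models at an unadjusted p below 0.05 in the fit of all groups. The call of 000078F:105509-119301 ended without forewing replicate 1 or hindwing replicate 2 (adjusted p = 0.0638 and 0.148), and that of 000009F:2925635-2927721 without hindwing replicate 1 or 3 (adjusted p = 0.0738 and 0.0751). That of 000017F:2036946-2042642 ended without forewing replicate 1 (log2 −1.69, adjusted p = 0.0664) or any hindwing library (adjusted p from 0.0751 to 0.197). These fits were unpaired. With all libraries and the replicate block, edgeR adjusted p was 0.00578, 3.48e-06 and 0.00614 for these models, in this order. The log2 fold change of 000078F:105509-119301 was −4.21 without forewing replicate 1 and −5.66 without hindwing replicate 3.

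Averaged over the 4 stages, 000025F:951192-952313 was higher in hindwings by a log2 fold change of 6.503 ± 0.25 (edgeR adjusted p = 4.82e-12, and 6.49 ± 0.17 with the replicate block). No other model met the naming rule. For the mean this rule asks for no overlap between all hindwing and all forewing libraries of the 4 stages. A model that changes between stages can fail it whatever its wing difference. Without replicate 2 of late forewings that group held 0 counts of 000025F:951192-952313. The fitted mean of 7.25 then depends on the prior count and is not a bound. In all 76 models differed, 18 higher and 58 lower in the hindwing, of which 20 had an absolute log2 fold change of 1 or more. The block called 1158 models, 359 higher and 799 lower, including all 76. Without hindwing replicate 3 of the 72 h pupa the unpaired count was 167, without both 72 h libraries numbered 3 it was 208, and without replicate 3 of larval forewings or hindwings it was 46 or 45.

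The change of the wing difference from stage to stage was tested next. From the 5th instar to the prepupa it changed for 428 models, 217 upward and 211 downward, of which 422 were also called between prepupal wings; the narrow majority turned under several alternatives, among them DESeq2 size factors, with 184 upward and 254 downward. From the prepupa to 72 h it changed for 536 models, 272 upward and 264 downward, of which 507 were also called between prepupal wings; with DESeq2 size factors the directions were 389 and 223, and without the filter the majority turned, with 170 and 200, as it did without some single libraries. Both changes contain the prepupal wing difference, so the lists are not independent of it or of each other. From 72 h to the late pupa the edgeR test called 0 models, with 291 at an unadjusted p below 0.05, and the DESeq2 Wald test called 4. With the replicate block the counts were 2387, 2789 and 94; on only the groups compared, the first were 826 and 54.

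The counts of changed wing differences depended on single libraries. From the 5th instar to the prepupa the count was 273 without replicate 1 of larval forewings and 255 without replicate 3 of these, 275 without replicate 1 of larval hindwings and 261 without replicate 2 of these, 250 without replicate 1 of prepupal forewings and 263 without replicate 3 of prepupal hindwings. From the prepupa to 72 h it was 311 without replicate 1 of prepupal forewings, 327 without replicate 3 of prepupal hindwings and 902 without replicate 3 of 72 h hindwings. From 72 h to the late pupa it was 1 without this last library.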

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

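The splits of the samples and the tests of explanations in this part were chosen after the results were seen; the tests of the change of the wing difference were planned. By an edgeR test of the change itself, the wing difference changed for 428 models from the 5th instar to the prepupa. From the prepupa to 72 h it changed for 536 models. Fitted on only the groups compared, the counts were 826 and 54, so the second count rests on fitting the libraries of the other stages as well. Of the named models, the change from the 5th instar to the prepupa passed for 000057F:507839-512115 (log2 −7.66 ± 2.01, SE, adjusted p = 0.0485) and for 000057F:536747-539676 (log2 −5.55 ± 1.48, adjusted p = 0.0472). Larval forewings held 0 and 4 counts of these models, so the fitted sizes depend on the prior count and are not bounds. The call of the former ended whichever of the 12 libraries was left out (adjusted p from 0.0518 to 0.338; log2 −6.97 without replicate 2 of larval hindwings). That of the latter ended without any 1 forewing library of either stage, replicate 2 or 3 of larval hindwings or replicate 2 of prepupal hindwings (adjusted p from 0.0613 to 0.263; log2 −4.74 without replicate 3 of larval forewings). With the replicate block the values were −7.39 ± 1.33 (adjusted p = 0.00340) and −5.82 ± 1.93 (adjusted p = 0.0633), and over all alternatives adjusted p ran from 0.000921 to 0.392 and from 0.00300 to 0.526.

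From the prepupa to 72 h the change passed for 000129F:89294-91831 (log2 2.39 ± 0.44, adjusted p = 0.00443; 2.50 ± 0.28 with the replicate block). It stood at 17.9 CPM ± 8.33 (SD, n = 3) in prepupal hindwings against 106 CPM ± 22.1 in forewings, and at 31.0 CPM ± 4.01 against 34.8 CPM ± 9.82 at 72 h. The call remained without any single library and ended in fits of only the groups compared, of numbers 2 and 3 and of numbers 1 and 3 (adjusted p from 4.28e-06 to 0.128 over the alternatives).

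The wings differed most in the prepupa. With every library thinned to 5795618 counts, 1227 models were called between prepupal wings, against at most 5 at the other stages. This argues against depth as the whole cause. With DESeq2 size factors 1394 were called. These factors moved the median log2 wing difference of all models by only −0.066, so an error shared by both scalings would not show. Mean TMM factors were 0.590 in prepupal forewings and 0.870 in prepupal hindwings, further apart than at any other stage, and scaling stays open. A candidate explanation is that hindwings stood earlier on the path from larva to prepupa when collected. Then hindwings would lie between the larval and the forewing level: of the 1370 called models, at least 73.9% had a wing difference opposite in sign to the step of the hindwing alone, taken from libraries of other numbers, against at most 51.1% for unrelated signs and at most 61.1% among models not called. A stronger response of the forewing gives such signs as well. This, a difference in timing between the wings, in cell composition or in the time of collection stay open and were not separated. The pattern did not extend to the next step: with all libraries, 48.4% of the called models had a wing difference opposite to the step from prepupa to 72 h.

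Other splits of the 6 libraries of a comparison into 3 and 3 make 10 with the real one, too few for a share under 0.05. The real and the highest other counts between the wings were 5 and 29 in the 5th instar, 1370 and 16 in the prepupa, 1 and 1449 at 72 h, and 4 and 3 in the late pupa; 2, 1, 7 and 1 of the 10 splits gave as many calls. The 1449 calls at 72 h point to a structure of the samples. Among the 3 other splits that part every pair of wings, the highest counts were 0, 1, 0 and 0, so the high counts came from splits that keep pairs together. In the steps, 1 split of 10, the real one, gave as many calls each time. In forewings the real and highest other counts were 7416 and 0, 6364 and 0, and 6932 and 1, and in hindwings 6084 and 0, 6444 and 0, and 6952 and 0.

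For the mean of the 4 stages, 2 of 60 splits, the real one included, gave at least 76 calls, with 198 the highest other. The numbers pair the wings, so the splits that part every pair are the closer comparison: 1 of 31, the real one, reached 76, with 64 the highest other. Chance can be excluded at 0.05 only for labels unrelated to the wings at every stage, the prepupa included. Splits that mixed the prepupal wings reached at most 3 and 10 others kept them apart, too few for a share under 0.05, so the splits do not show a difference in the mean beyond that of the prepupa.

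For the changes of the wing difference, 2 of 50 splits in the unpaired fit reached 428 in the first step (highest other 469) and 2 of 50 reached 536 in the next (highest other 679). Among the 27 splits that part every pair, 2 and 1 did, the highest others being 469 and 447. Splits that mixed the prepupal wings reached at most 1 and 158; the higher counts came from splits that kept the prepupal difference, so they are no test of the change alone. With the replicate block and wings swapped within numbers, 2 of 32 splits reached 2387 in the first step (highest other 2763, and 0 where the prepupal wings were mixed). In the next, 1 of 32, the real one, reached 2789 (highest other 2594, and 12 where they were mixed). Only 8 of the 32 keep the prepupal wings apart, of which 2 and 1 reached the counts, too few for a share under 0.05, so these splits do not decide on chance for either change. Exchanging whole pairs between the stages keeps the pairing and tests the change itself, but makes 10 splits, too few for a share under 0.05; the real and highest other counts were 2387 and 0, and 2789 and 14, with 1 split of 10, the real one, reaching the count each time.

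From 72 h to the late pupa the unpaired edgeR count is 0 (291 models at an unadjusted p below 0.05, 4 by the DESeq2 Wald test), which 50 of 50 splits reach whatever they hold (highest 465, and 7 among those that part every pair), so they decide nothing. With the replicate block 94 models were called, and 4 of 32 splits with wings swapped within numbers gave as many (highest other 192), so chance cannot be excluded. Exchanging pairs between these stages gave at most 5, again in 10 splits, of which 1, the real one, reached 94.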

How the results depend on the processing

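Fits with 2 of the 3 replicate numbers, and without both 72 h libraries numbered 3, were chosen after seeing the data; the other alternatives were planned. Of the counts of called models under the alternatives, 184 stayed within 1.5 times the reported count, all those of the 6 stage steps among them, and 69 did not. Other counts were those at an absolute log2 fold change of 1 or more, of models called in both wings in the same direction, and of models highest at a stage. Of these other counts together, 60 did not stay within 1.5 times. No named model changed direction. Named models passed the threshold in every stage step under every alternative; 94 values of 11 named wing models, changes of the wing difference included, no longer passed. The model 000025F:951192-952313 passed throughout in the 5th instar, the prepupa and the mean, but not at 72 h or in the late pupa in fits of only the groups compared or with numbers 2 and 3 of every group.

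Wing counts follow in the order 5th instar, prepupa, 72 h, late pupa, mean of stages. With the replicate block, which follows the pairing of the wings, they were 131, 4107, 358, 61 and 1158, and the changes of the wing difference were 2387, 2789 and 94. The DESeq2 Wald test gave 40 in the 5th instar, 23 at 72 h, 19 in the late pupa, 280 for the mean, and 872, 987 and 4 for the changes. Without the filter the 5th instar count was 3. Fitted on only the groups compared, counts were 1 in the 5th instar, 0 at 72 h, 0 in the late pupa, and 826 and 54 for the first changes of the wing difference; the cause was not tested. With numbers 2 and 3 of every group the wing counts were 1, 371, 0, 0 and 1 and the first changes 8 and 26; with numbers 1 and 3 they were 1, 437, 1, 1 and 1, and 6 and 5; with numbers 1 and 2 they were 3, 836, 1, 1 and 36, and 117 and 348. These fits hold fewer samples. Without both 72 h libraries numbered 3 there were 66 calls at 72 h, 208 for the mean and 1 for the last change of the wing difference; the cause was not tested.

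Leaving out single libraries gave 2 to 4 calls in the 5th instar, 858 to 1149 in the prepupa, 1 to 131 at 72 h, 2 to 4 in the late pupa and 45 to 167 for the mean. The changes ranged from 250 to 377, 311 to 902 and 0 to 1. Forewing steps ranged from 6680 to 6922, 5675 to 6060 and 6218 to 6504, hindwing steps from 5243 to 5439, 5744 to 6076 and 6207 to 6549. The highest values at 72 h (131), for the mean (167) and for the change from prepupa to 72 h (902) came without hindwing replicate 3 of the 72 h pupa; the cause was not tested. Among simulated changes, the unpaired fit recovered 16% of 2-fold differences between prepupal wings, so it mostly missed small differences there. The simulation changed 100 models by 2-fold and 100 by 4-fold, against 1370 called between real prepupal wings. The adjusted p depends on how many models change, so this recovery does not carry over to the real comparisons. Recovery with the replicate block was not simulated. Gene list tests by camera and fry were not run, since the deposited files do not pair the models with gene names.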

Other observations

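All tests of explanations in this part were chosen after the results were seen. With the wings paired by number, 8 models were called in the same direction at 3 or more stages, 3 of them higher and 5 lower in the hindwing; all are named here after their values were seen. Besides 000025F:951192-952313, the models 000243F:131306-140032 and 000243F:146466-149765 were higher in hindwings in the 5th instar (log2 2.41 ± 0.31 and 2.33 ± 0.49, SE), the prepupa (1.85 ± 0.16 and 1.94 ± 0.20) and at 72 h (1.17 ± 0.18 and 1.18 ± 0.26). In the late pupa their values were 0.01 ± 0.18 and 0.26 ± 0.29, not past the threshold. The paired test of the change from 72 h gave −1.16 ± 0.26 (adjusted p = 0.0763) and −0.92 ± 0.39 (adjusted p = 0.463) and called neither. Lower in hindwings were 000001F:234692-243615 (log2 −1.43, −0.99 and −0.82 in the 5th instar, the prepupa and at 72 h, but −0.12 in the late pupa) and 000012F:2739492-2747437 (−1.02, −1.65 and −0.85 at the later 3 stages, and −0.68 in the 5th instar). The others were 000086F:1589853-1600355 (−0.97, −0.73 and −1.55) and 000259F:296788-301306 (−2.05, −1.34 and −2.18), both in the 5th instar, the prepupa and the late pupa, and 000094F:1094836-1098055 (−0.47, −0.61 and −0.66) in the 5th instar, at 72 h and in the late pupa. At the remaining stage, not past the threshold, 000086F:1589853-1600355 was at 0.30 and 000259F:296788-301306 at −2.05 at 72 h, and 000094F:1094836-1098055 at 0.06 in the prepupa. The paired test of the change passed for 000001F:234692-243615 from 72 h to the late pupa (0.70 ± 0.14, adjusted p = 0.0394). It also passed for 000086F:1589853-1600355 from the prepupa to 72 h (1.03 ± 0.27, adjusted p = 0.0181) and on to the late pupa (−1.85 ± 0.31, adjusted p = 0.0220), and for 000094F:1094836-1098055 into the prepupa (0.53 ± 0.14, adjusted p = 0.0165) and out of it (−0.67 ± 0.14, adjusted p = 0.00466). The unpaired test called none of these 5 changes (adjusted p of at least 0.567). The changes from 72 h to the late pupa belong to the 94 paired calls that 4 of 32 splits with swapped wings matched in number, so chance cannot be excluded for that list.

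Neighbouring models on a contig often changed together. A run of 18 models between positions 1811349 and 1956194 of contig 000019F, 2 of which overlap another model, rose in both wings from a summed 60.7 CPM ± 23.8 (SD, n = 6 libraries) in the 5th instar to 12861 CPM ± 3672 in the prepupa and fell to 81.0 CPM ± 48.9 at 72 h. The SDs of summed CPM pool both wings of a stage, which are paired by number, so they mix wing differences with replicate spread. A run of 17 models on contig 000238F (195029 to 671955) rose from a summed 57.9 CPM ± 68.7 in the prepupa to 230266 CPM ± 43760 at 72 h. The run that fell from 72 h to the late pupa on this contig, also 17 models (168374 to 582415), went to 100.05 CPM ± 41.0.

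In runs of at least 4 neighbouring models called in both wings in the same direction lay 886 models for prepupa against 5th instar, 665 for 72 h against prepupa and 1078 for late pupa against 72 h. The highest values among 1000 random orders of the models were 209, 148 and 296. Without overlapping models each step still exceeded its highest random order, by at least 414 models, which argues against shared reads of overlapping models as the whole cause. A transcript split over several models stays open: neighbours in runs differed in level by a median of at least 1.57 on the log2 scale, but poly-A selected reads can cover parts of a transcript unevenly. Related genes that share reads, and neighbours regulated together, were not tested, for want of sequences and names.

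Libraries numbered 2 detected most models of their group in 8 of 8 groups. With all libraries thinned to the smallest this held in 7 of 8, the exception being late pupal hindwings, which argues against deeper sequencing as the whole cause. A low background that grows with model span is a candidate explanation: among 5332 low-count models, the ratio of counts on long models (median span 11611 bp) to short ones (919.5 bp) was highest in number 2 in 7 of 8 groups, with the same exception, and in prepupal forewings it was 1.89, against 1.33 and 1.34 in the other libraries. RNA carried over from prepupal libraries stays open: 254 models higher in the prepupa than at any other stage by at least 3 (log2) were most often highest in number 2 in 6 of 6 groups of the other stages, though by summed CPM in 4 of 6. Models highest in the late pupa were so in 6 of 6 as well, and those of the 5th instar and 72 h in 4 of 6 each, so carry-over from prepupal libraries and a wider source cannot be told apart, and no biological explanation was tested.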
